A study of Homo sapiens with 6 samples.

How the data were processed

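Single-nucleus RNA was measured in 6 libraries from teratomas of the H1 human embryonic stem cell line: WT, KO and ΔATG (DATG), 2 each, with groups and replicate numbers taken from the sample titles. The groups, tests, gene lists, markers and the rule for named genes were fixed before the data were examined. Per the labels' protocols, frozen tumours were dissociated to nuclei on a Singulator and libraries were made with the 10x Genomics 3' chemistry for single cells. The authors deposited, for each library, a matrix of raw UMI counts per gene and barcode with its gene and barcode lists, and these counts are not normalized. They were made with Cell Ranger 8.0.1 per the submitters' processing notes, while the matrix headers name 8.0.0. The notes name GRCh38 and GRCm38 as genome builds, while the mouse features carry the prefix GRCm39, so no mouse coordinate is given. The settings of the counting, introns and strand included, are not given in the sources used here. The gene annotation used here for human coordinates is GENCODE 29 on GRCh38, matched by gene identifier.

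A barcode was kept as a nucleus with at least 500 UMIs and 300 genes, and as human or mouse when at least 90% of its UMIs fell on that species. Barcodes between the species were left out as mixed. Doublets were called against simulated doublets with an assumed rate of 0.8% per 1000 nuclei. That removed 5009 barcodes, 6.03% to 11.0% of human nuclei per library. No limit on mitochondrial RNA was set. Human nuclei were scaled to 10000 UMIs, and 2000 variable genes, without the 13 mitochondrial ones, gave 30 principal components, a graph of 20 neighbours and Leiden clusters at resolution 1. A cluster was named "-like" from fixed marker lists, when at least 3 markers stood at least 2-fold above the other clusters and at 20 CPM or more, these were over 1/3 of the list, and its 10 leading genes did not hold more markers of another class. A cluster with under 1/3 of the median depth also needed a marker among those genes. Of 30 human clusters 6 stayed unnamed, the leading genes of some of which are not reported here, and the 15 mouse clusters were treated in the same way. Class names were rebuilt here, since no annotation by the authors was used.

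UMI counts were summed per library over human nuclei, over the nuclei of a class, or over mouse nuclei, because nuclei are not replicates. The main test was the robust quasi-likelihood F test of edgeR 4.0.16 on R 4.3.3, with TMM scaling, its default filter on low counts, 1 mean per group, all 6 libraries in the fit, and Benjamini-Hochberg adjusted p under 0.05 as the threshold. CPM values are scaled by the TMM library sizes unless given per library. Class shares were tested with edgeR on numbers of nuclei with the total as offset. The 3 classes tested within were those with the largest minimum number of nuclei over the libraries. The host share was tested with an exact permutation test. LNCPRESS1 was tested with no filter. Correlation of effects was set beside 20 simulations of unchanged groups against the WT libraries, and the overlap of DESeq2 calls beside 8. In those 8 all 6 libraries, WT included, were simulated, with each gene drawn independently. Intervals are exact (Clopper-Pearson, 95%) and cover counting error only.

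Gene lists were tested with camera of limma 3.58.1, with a preset correlation of 0.01 between genes and adjustment over lists in each comparison, and again with an estimated correlation and with fry. There were 20 fixed lists (pluripotency, p53 targets, glycolysis and hypoxia, early ectoderm, mesoderm and endoderm regulators, HOX genes, S phase, G2 and M phase, ribosomal proteins, mitochondrially encoded, immediate early and heat shock, WNT, BMP and TGF-beta, NOTCH, Hedgehog, FGF and ERK, imprinted genes, interferon response, collagens and matrix) and 30 lists of class markers. Of these 49 had at least 5 tested genes, and the adipocyte list, with 4, was not tested. Many markers are shared between related lists, and the pluripotent markers are part of the pluripotency list.

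Genes were named by a fixed rule. In each whole-teratoma comparison up to 8 genes per direction with the largest fold change were named among those past the threshold, with a mean of at least 5 CPM, both libraries of a group beyond both of the other, and a symbol other than a clone name. Where fewer passed, the list was filled to 4 with the smallest unadjusted p and said not to pass. For each gene list the 3 members with the smallest unadjusted p could be named, and for the host and within classes 5 genes per direction with no filling. XIST and Y-linked genes were left out.

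The tests were also run on simulated counts with known changes, for KO vs WT. With the spread of all 6 libraries over 25670 genes, edgeR called 0 of 65 genes changed 2-fold, 20 of 69 changed 4-fold and 58 of 66 changed 8-fold, with 9 false calls. DESeq2 1.42.0 called 5, 57 and 65, with 117 false calls. With the spread of the WT and KO libraries over 25680 genes, edgeR called 11, 66 and 66 with 27 false calls, and DESeq2 19, 67 and 66 with 43. Camera recovered the list that was moved and called 0 others.

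Alternatives tried were RLE in place of TMM scaling, DESeq2, no filter on low counts, only the libraries of the compared groups, the replicate number as a block, each library left out in turn, at least 1000 UMIs, doublets kept, equal numbers of nuclei (5208), Leiden resolutions of 0.5 and 2, and purity of 80% for the host share. A group with a library left out has 1 library, assumed to vary like the other groups, so its calls describe that library alone. Added after the data were seen were purity of 80% for the whole-teratoma comparisons and of over 50% for the host share, under 5% mitochondrial UMIs, class shares in the libraries of the compared groups alone, and a different WT library for each comparison in the correlation of effects. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, igraph 0.11.9 and leidenalg 0.10.2 did the clustering, and matplotlib 3.10.9 the figures.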

Results

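The study asked what loss or alteration of LNCPRESS1, a long non-coding RNA, does to tissue formed by human embryonic stem cells. Background work describes LNCPRESS1 as repressed by p53 and as a partner of the deacetylase SIRT6 in pluripotent cells. H1, an established embryonic stem cell line, was used as wild type (WT), as an LNCPRESS1 knockout (KO) and as a line labelled ΔATG (DATG), whose sequence change the labels do not describe. Cells mixed with matrigel grew into teratomas, tumours that hold tissues of all germ layers, in the flank of immunodeficient NSG mice. Nuclei were isolated from frozen tumours, and droplet libraries counted RNA molecules by unique molecular identifier (UMI) on a joint human and mouse reference. There were 2 libraries in each of the 3 groups. The labels do not say whether the libraries of a group come from separate tumours or clones, so p-values here measure only the spread between these samples.

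The libraries held from 35785812 to 47574535 UMIs and from 6504 to 13489 barcodes. After filtering, 49021 human nuclei remained, with 5208 and 10911 in WT, 9204 and 7342 in KO, and 10812 and 5544 in DATG (replicates 1 and 2). Their median depth lay between 2423 and 3819 UMIs, and the summed human UMIs per library between 19097400 and 32646649. The 30 human clusters gave 24 that carried enough fixed markers for a name, in 16 classes, and 6 that stayed unnamed and held 21.0% ± 7.24 of WT, 22.3% ± 7.55 of KO and 11.6% ± 3.47 of DATG nuclei (SD, n = 2, as for all values after a ± sign). The DATG pair stood apart from each other: their log2 CPM correlated at 0.903, against 0.976 for the WT pair and 0.978 for the KO pair. The first principal component, 65.7% of the variance, separated DATG replicate 2 from the other libraries.

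LNCPRESS1 lies on chromosome 7 of GRCh38, at 101299578 to 101301346 on the plus strand, and GENCODE 29 gives it 2 exons (101299578 to 101299866 and 101300769 to 101301346) and the type lincRNA. Human nuclei held 6 and 2 of its UMIs in WT, 3 and 0 in KO, and 0 and 3 in DATG. That is 8 of 59403751 UMIs in WT, 3 of 61115676 in KO and 3 of 51744049 in DATG. In CPM the groups stood at 0.135, 0.0491 and 0.0580. The log2 fold change was -1.37 for KO vs WT (SE 1.51, edgeR adjusted p = 1), -0.94 for DATG vs WT (SE 1.54, adjusted p = 1) and 0.43 for DATG vs KO (SE 1.80, adjusted p = 0.971). Pluripotent-like nuclei held 3, 1 and 1 of these UMIs in WT, KO and DATG. There were 30 and 37 such nuclei in WT, 145 and 2 in KO, and 0 and 114 in DATG, so the libraries differed in this class. At these UMI counts a difference was not detectable and the labels could not be checked. The labels also do not say which part of the gene was deleted, and a 3' tag outside that part would check nothing.

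In KO teratomas, markers of gut, liver, other epithelium and blood vessels were lower than in WT, and markers of neurons, neural progenitors and HOX genes were higher. The gut epithelium list fell, with a median log2 fold change of -2.74 and 0 of 14 members above 0. The hepatocyte list (-1.78), the early endoderm regulators (-1.56, 3 of 18 above 0) and the general epithelium list (-1.52) fell as well. The neuron list rose by a median of 1.20 and the HOX genes, which set position along the body axis, by 1.35. Limma's camera test with a preset correlation between genes gave adjusted p = 2.3e-18 for gut, 4.1e-13 for hepatocyte, 7.7e-09 for endoderm regulators, 9.7e-10 for epithelium, 7.8e-12 for neuron and 1.5e-13 for HOX genes. None of these calls held with an estimated correlation: adjusted p = 0.554 for gut, hepatocyte and endoderm regulators, 0.711 for epithelium and HOX genes, and 0.723 for neuron. With 1 library left out these lists kept their calls, with the hepatocyte median at -1.10 without WT replicate 2 and the HOX median at 0.83 without KO replicate 1.

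Among the gut genes, FABP2, a fatty acid binding protein of enterocytes, stood at 4.52 ± 0.0841 CPM in WT and 0.176 ± 0.112 in KO. APOA4, an intestinal apolipoprotein, stood at 8.37 ± 0.869 and 1.26 ± 0.645. PHGR1 had a log2 fold change of -5.07. Of the gut genes 7 passed when adjusted over the list alone, and 0 over all genes. Of the hepatocyte genes 3 passed when adjusted over the list alone: the fetal plasma protein AFP stood at 197 ± 84.2 CPM in WT and 58.1 ± 25.3 in KO. In the endoderm list the pancreas and duodenum regulator PDX1 (log2 fold change -3.79) was the 1 gene that passed when adjusted over the list alone. GATA4, which directs endoderm and heart, stood at 76.8 ± 0.656 CPM in WT, 7.83 ± 2.02 in KO and 19.9 ± 22.5 in DATG.

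Endothelial markers fell too, by a median of -1.10 with 0 of 12 above 0 (camera adjusted p = 3.2e-09; adjusted p = 0.554 with an estimated correlation). Of these, 4 passed when adjusted over the list alone, and the junction protein PECAM1 had 18.6 ± 0.0604 CPM in WT and 3.74 ± 2.09 in KO. The blood and immune list (median -1.11, MRC1 -2.53), the choroid plexus list (-1.10), the collagens and matrix list (-0.75, COL14A1 -1.26) and the mesenchyme list (-0.59) fell, with camera adjusted p of 7.2e-04, 0.0419, 7.8e-07 and 0.0141. With an estimated correlation their adjusted p = 0.734, 0.734, 0.734 and 0.788. The imprinted genes fell by a median of -0.16 and a mean of -0.55 (adjusted p = 0.0147; adjusted p = 0.734 with an estimated correlation). MEG3 (-3.50) and MEG8 (-2.94), non-coding RNAs of the imprinted DLK1 locus, were the 2 members that passed when adjusted over the list alone. Both are among the leading genes of an unnamed cluster that held 4.88% ± 2.71 of WT, 0.336% ± 0.430 of KO and 0.337% ± 0.136 of DATG nuclei, so their fall may come from the loss of that cluster. Apart from the endothelial list, each call in this paragraph was lost with 1 library left out. The lists that then did not pass were, without WT replicate 1, choroid plexus (-0.33), without WT replicate 2, blood and immune (0.40), mesenchyme (-0.086) and imprinted genes (-0.066), and without KO replicate 1, blood and immune (-0.63), collagens and matrix (-0.26), mesenchyme (-0.17) and imprinted genes (0.016). Without KO replicate 2 choroid plexus (-0.87) did not pass, and without either DATG library mesenchyme (-0.60) and imprinted genes (-0.17) did not. Other medians moved by over 1.5 times: blood and immune to -1.82, mesenchyme to -0.99 and imprinted genes to -0.51 without WT replicate 1, collagens to -0.36 without WT replicate 2, and blood to -2.63, collagens to -1.44, mesenchyme to -1.34 and imprinted genes to -0.35 without KO replicate 2.

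On the higher side, all 18 neuron markers were above 0. NRXN3, a presynaptic adhesion protein, stood at 468 ± 111 CPM in WT and 1260 ± 86.7 in KO, and the synaptic calcium sensor SYT1 at 372 ± 61.9 and 831 ± 191. All 16 neural progenitor markers were above 0 as well (median 0.62), as were 21 of 23 early ectoderm regulators (0.60), among them the eye and forebrain regulator PAX6 (0.86). Of the HOX genes 34 of 37 were above 0, with HOXC10 at 2.31 and HOXA4 at 2.01. Skeletal muscle markers rose by 0.78 with 12 of 13 above 0, among them the myogenic regulator MYOG (2.34). The 1 member that passed when adjusted over the list alone was lower in KO, against the direction of the list. The muscle median was 1.73 without WT replicate 1, 0.35 without WT replicate 2, where it did not pass, and 0.47 without KO replicate 1. Mitochondrially encoded genes rose by 0.30, but did not pass without WT replicate 2 (-0.056), KO replicate 1 (0.048) or either DATG library (0.26), and stood at 1.10 without WT replicate 1 and 0.56 without KO replicate 2. The camera adjusted p was 7.8e-07 for progenitors, 4.8e-06 for ectoderm regulators, 1.4e-04 for skeletal muscle and 0.0419 for mitochondrial genes. With an estimated correlation these were adjusted p = 0.711, 0.711, 0.734 and 0.941.

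The shares of nuclei ran in the same directions without passing a test. Gut epithelium-like nuclei made up 6.71% ± 1.29 of WT and 0.407% ± 0.407 of KO (log2 fold change -4.04, edgeR adjusted p = 0.514). Neuron-like nuclei made up 7.63% ± 0.738 and 20.9% ± 2.44 (1.45, adjusted p = 0.531), endothelial-like nuclei 1.73% ± 0.00289 and 0.380% ± 0.137 (-2.19, adjusted p = 0.514), and choroid plexus-like nuclei 6.76% ± 0.699 and 2.42% ± 0.230. Neural and ectoderm classes together, with squamous epithelium-like and melanocyte-like nuclei included, were 26.9% of WT and 42.0% of KO nuclei. Of the 16 classes edgeR called 0 in KO vs WT, with 0 at an unadjusted p under 0.05, and no second tool was run on shares. In simulations with this spread, where only the gut epithelium-like share was changed, the test recovered 4% of 8-fold rises and 33% of 32-fold rises in KO. A 32-fold rise from the 4.21% of this class in all nuclei is more than a real library can hold. Falls, the direction seen here, were not simulated, so the power to call them is not known.

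**Figure D1:**
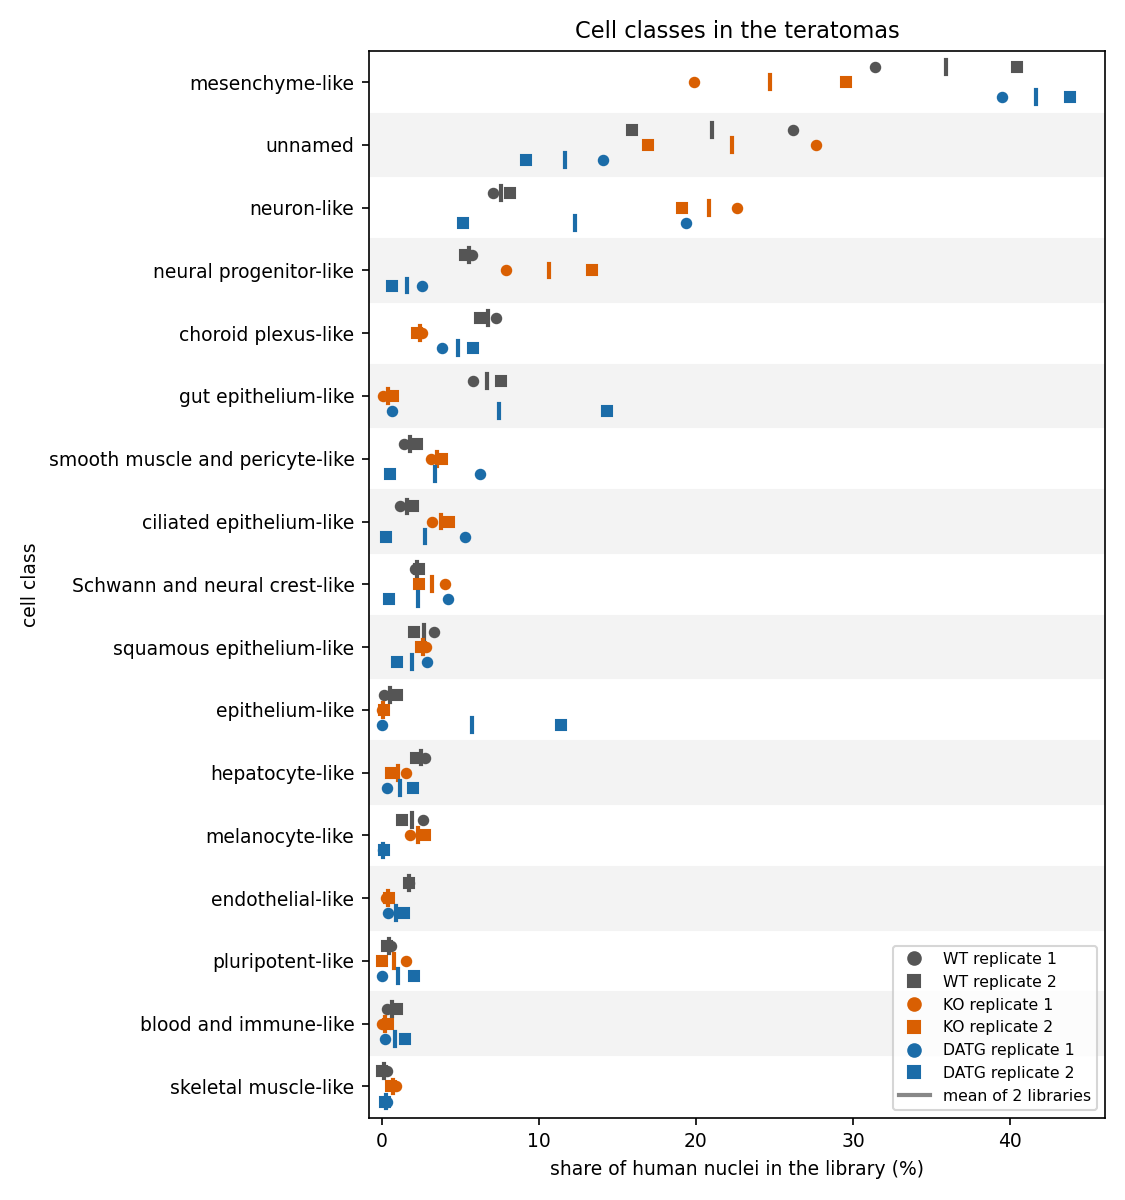
Share of human nuclei in the library (percent, x axis) in each class and in the unnamed clusters (y axis), with 1 point per library, coloured by group, and a bar at the mean of 2 libraries. Gut epithelium-like nuclei stand at 0.675% and 14.3% in the DATG pair, and neuron-like nuclei at 19.4% and 5.18%.

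Gene by gene, edgeR called 0 of 26146 genes in KO vs WT when all 6 libraries shared a spread (1264 at an unadjusted p under 0.05), and DESeq2 called 156, of which 4 were higher and 152 lower. The genes with the smallest p did not pass in edgeR (adjusted p from 0.746 to 0.998). ZNF667, a zinc-finger gene on chromosome 19 (56439325 to 56478065), stood at 7.80 ± 0.733 CPM in WT and 0.145 ± 0.0693 in KO, a log2 fold change of -5.72 (SE 0.52). Its antisense partner ZNF667-AS1, named after its values were seen, stood at 7.32 ± 0.976 and 0.385 ± 0.0443 CPM, and whether the counting used strand is not given in the sources used here. ZNF585B, on the same chromosome (37181579 to 37218153), stood at 11.3 ± 0.818 and 1.81 ± 0.0965 (-2.64) and has a near-identical copy, ZNF585A, so its value is uncertain. FOLH1, a folate hydrolase, stood at 10.8 ± 2.05 and 0.40 ± 0.11 (-4.74), and APOA1, the main protein of high-density lipoprotein, at 58.8 ± 9.89 and 12.0 ± 2.40 (-2.30). Higher in KO were NELL1, a secreted glycoprotein, at 1.24, the neural gene BRINP1 (1.04), the protease ADAMTS18 (0.96) and the antisense RNA LHX5-AS1 (1.24). DESeq2 gave adjusted p = 3.1e-16 for ZNF667, 1.1e-08 for ZNF585B, 1.4e-09 for FOLH1, 6.9e-06 for APOA1 and 0.00353 for NELL1.

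The count depended on the DATG pair, whose spread entered the shared estimate: the common coefficient of biological variation was 38.6% with all 6 libraries and 24.4% without either DATG library. With the 4 WT and KO libraries alone edgeR called 436 of 25550 genes, 96 higher and 340 lower in KO, and 133 of them were among DESeq2's 156. Leaving out DATG replicate 1 gave 592, and without DATG replicate 2 538. The genes named next come from the 4-library fit and were chosen after its count was seen. Lower in KO were BTNL3 (-5.49) and BTNL8 (-5.29), butyrophilin-like proteins of gut epithelium, the brush border enzyme SI (61.2 ± 27.4 CPM in WT, 2.36 ± 2.04 in KO), the mucin MUC13 (-4.60), the pancreatic colipase CLPS (-4.47), the liver enzyme CYP2C19 (-4.43), ADGRG7 (-4.41) and FOLH1 (-4.76). Higher in KO were the hypothalamic regulator OTP (1.96 ± 0.444 CPM in WT, 12.2 ± 4.66 in KO; 2.64), PRDM8 (2.41), HOXD3 (2.35), GPM6A-DT (2.02), the choline transporter SLC5A7 (1.87), HOXA3 (1.81), UNCX (1.79) and NRSN1 (1.77). Of the gut markers 9 of 13 were called lower in that fit, of the endoderm regulators 7 of 17, and of the endothelial markers 3 of 12, while 7 of 18 neuron markers and 3 of 34 HOX genes were called higher.

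**Figure D2:**
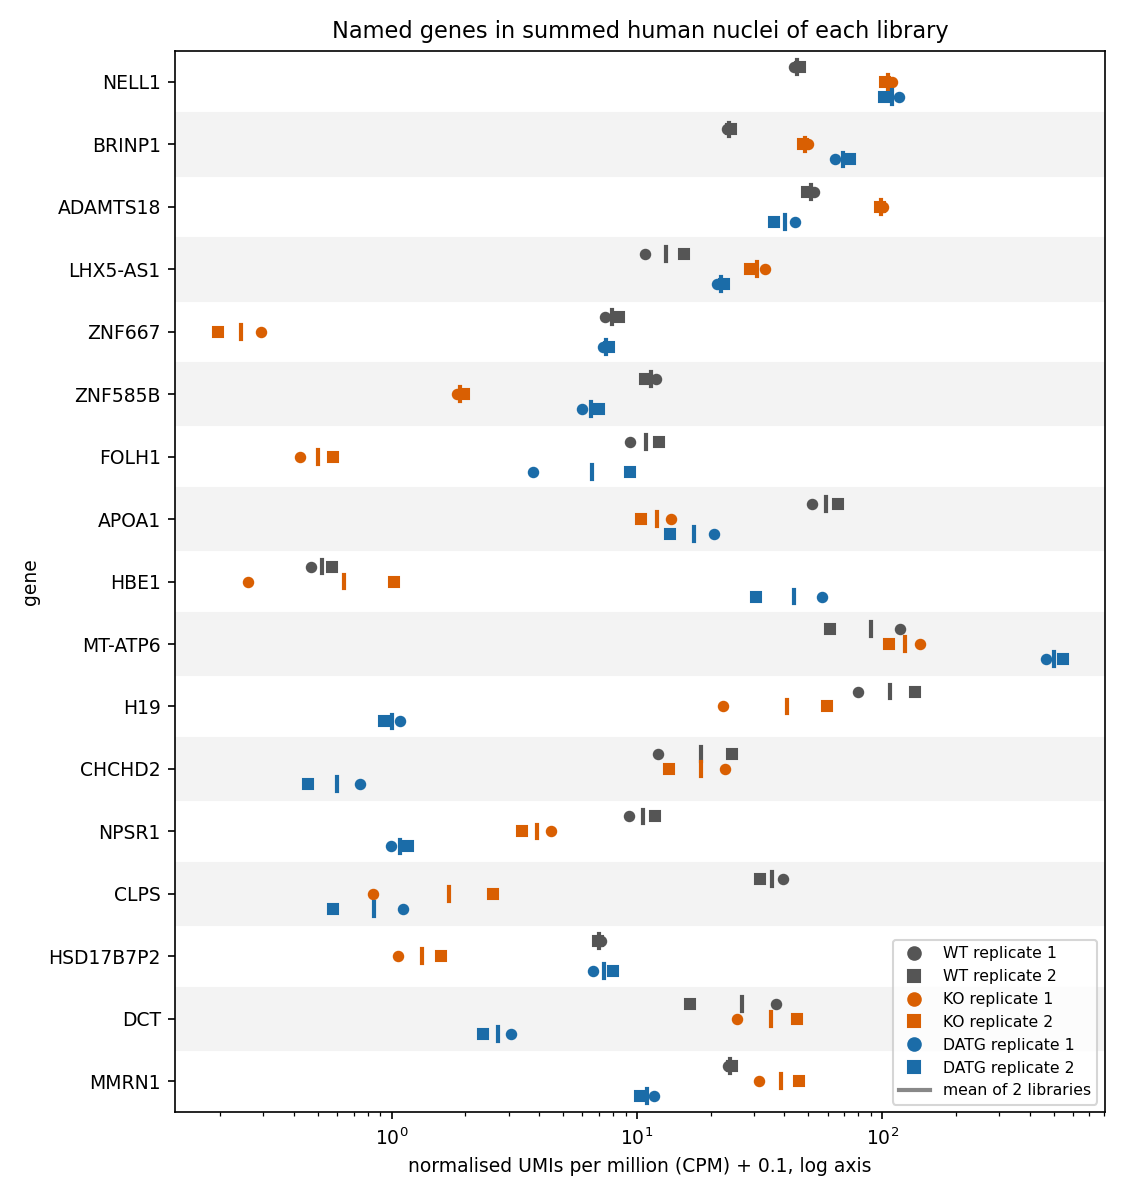
CPM plus 0.1 (x axis, log scale) of the named genes (y axis) in summed human nuclei, with 1 point per library, coloured by group, and a bar at the mean of 2 libraries. Before the added 0.1, mean ZNF667 is 0.145 CPM in KO, and mean H19 and CHCHD2 are 0.907 and 0.501 CPM in DATG.

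In DATG teratomas, mitochondrially encoded genes and HOX genes were higher than in WT, and pigment cell markers were lower. The mitochondrial list rose by a median log2 fold change of 2.49 with all 13 genes above 0, and all 13 passed when adjusted over the list alone. MT-CO2, a subunit of cytochrome oxidase, stood at 158 ± 64.2 CPM in WT and 646 ± 110 in DATG. The HOX list rose by 1.28 with 34 of 37 above 0, but by 0.14 without DATG replicate 1 (camera adjusted p = 0.0912), and HOXC8 stood at 5.09 ± 1.29 and 17.9 ± 4.12 CPM. Melanocyte markers fell by -1.28 with 0 of 8 above 0 and 4 past the threshold when adjusted over the list alone, among them the melanosome protein PMEL, at 27.0 ± 4.12 and 6.95 ± 3.04 CPM. Camera gave adjusted p = 1.1e-52 for mitochondrial genes, 1.4e-14 for HOX genes and 8.0e-11 for melanocyte markers. With an estimated correlation these were adjusted p = 0.521, 0.763 and 0.521. The melanocyte median without DATG replicate 1 was -2.39.

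Both DATG libraries had more mitochondrial RNA per nucleus, a usual measure of quality in nuclei: 0.489% and 0.483% of human UMIs, against 0.172% and 0.0764% in WT and 0.182% and 0.117% in KO. Mouse nuclei of the same libraries had 2.08% and 1.31%, against 0.211% and 0.377% in WT and 0.688% and 0.499% in KO. Ribosomal protein genes rose by 0.53 with 73 of 73 above 0 (camera adjusted p = 1.0e-09; adjusted p = 0.781 with an estimated correlation), and RPL37A stood at 134 ± 28.4 CPM in WT and 255 ± 66.0 in DATG. The ribosomal median did not pass without DATG replicate 1 (-0.57) or WT replicate 1 (0.11), and was 1.08 without DATG replicate 2 and 1.06 without WT replicate 2.

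**Figure D3:**
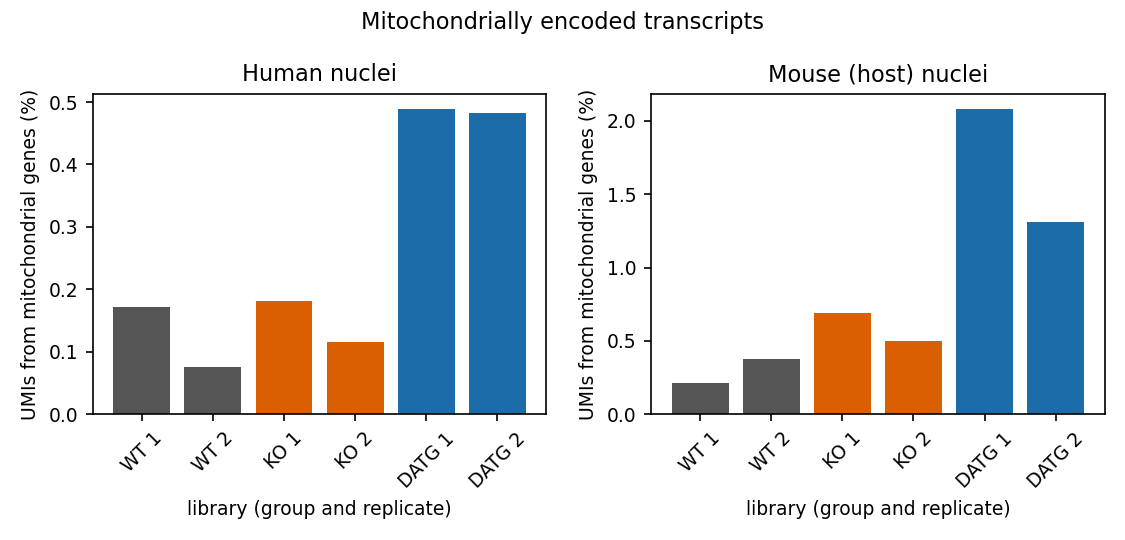
Mitochondrially encoded UMIs as a percent of UMIs (y axis) in human nuclei (left) and mouse nuclei (right), with 1 bar per library (x axis), coloured by group. Group means in human nuclei are 0.124% in WT, 0.149% in KO and 0.486% in DATG, and in mouse nuclei 0.294%, 0.594% and 1.70%.

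Further lists higher in DATG were neuron (0.66), chondrocyte (0.63, with the cartilage collagen COL11A1 at 0.82), mesenchyme (0.62, 16 of 16 above 0) and collagens and matrix (0.54). The camera adjusted p was 0.00235, 0.0105, 3.0e-04 and 0.00741, and with an estimated correlation adjusted p = 0.781, 0.763, 0.781 and 0.828. Lower were the endothelial list (-0.87), the hepatocyte list (-0.77, with the plasma protein ALB at 52.8 ± 36.8 CPM in WT and 11.1 ± 2.56 in DATG), retinal pigment epithelium (-0.69), retina (-0.49), gut epithelium (-0.44) and neural progenitor (-0.35) lists. Their camera adjusted p was 0.00237, 6.2e-05, 0.00741, 0.00741, 0.00235 and 0.00541. With an estimated correlation the adjusted p = 0.763 for endothelial, pigment epithelium and retina and 0.781 for hepatocyte, gut and progenitor. TRPM1, a channel of pigment cells, had a log2 fold change of -4.11, the eye field regulator RAX -3.20 and the forebrain regulator LHX2 -1.95. The early ectoderm list fell by -0.12 (adjusted p = 0.0450) and the early endoderm list by -0.028, with a mean of -0.54 (adjusted p = 0.0325), both at adjusted p = 0.781 with an estimated correlation. PDX1 alone passed over the endoderm list alone. Without DATG replicate 1 the medians turned to 0.37 for endoderm, -0.57 for neuron, 0.15 for gut and -0.46 for chondrocyte, and without WT replicate 1 that of pigment epithelium to 0.19. Every call in this paragraph was lost with at least 1 library left out. Those lost with DATG replicate 1 left out were the 4 that turned and early ectoderm (-0.83), collagens (0.68), retina (-1.31), pigment epithelium (-2.19), mesenchyme (0.80), endothelial (-0.57) and hepatocyte (-0.68). With DATG replicate 2 left out, early ectoderm (-0.24), collagens (0.12), neural progenitor (-0.19), retina (-0.54) and pigment epithelium (-0.61) did not pass. With WT replicate 1 left out, early ectoderm (0.0048), early endoderm (-0.086), collagens (0.21), neural progenitor (-0.20), pigment epithelium (0.19), mesenchyme (0.28), chondrocyte (0.67) and gut (-0.052) did not, with WT replicate 2 left out, early endoderm (0.084) and hepatocyte (-0.31) did not, and without either KO library early ectoderm (-0.13) did not. Medians that passed but moved by over 1.5 times were those of endoderm (-1.76), neuron (1.27), mesenchyme (0.28) and gut (-2.12) without DATG replicate 2, of neural progenitor (-0.88) without DATG replicate 1, and of early ectoderm (-0.29), collagens (0.96), neural progenitor (-0.60), retina (-0.79), mesenchyme (1.06) and gut (-0.75) without WT replicate 2.

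**Figure D4:**
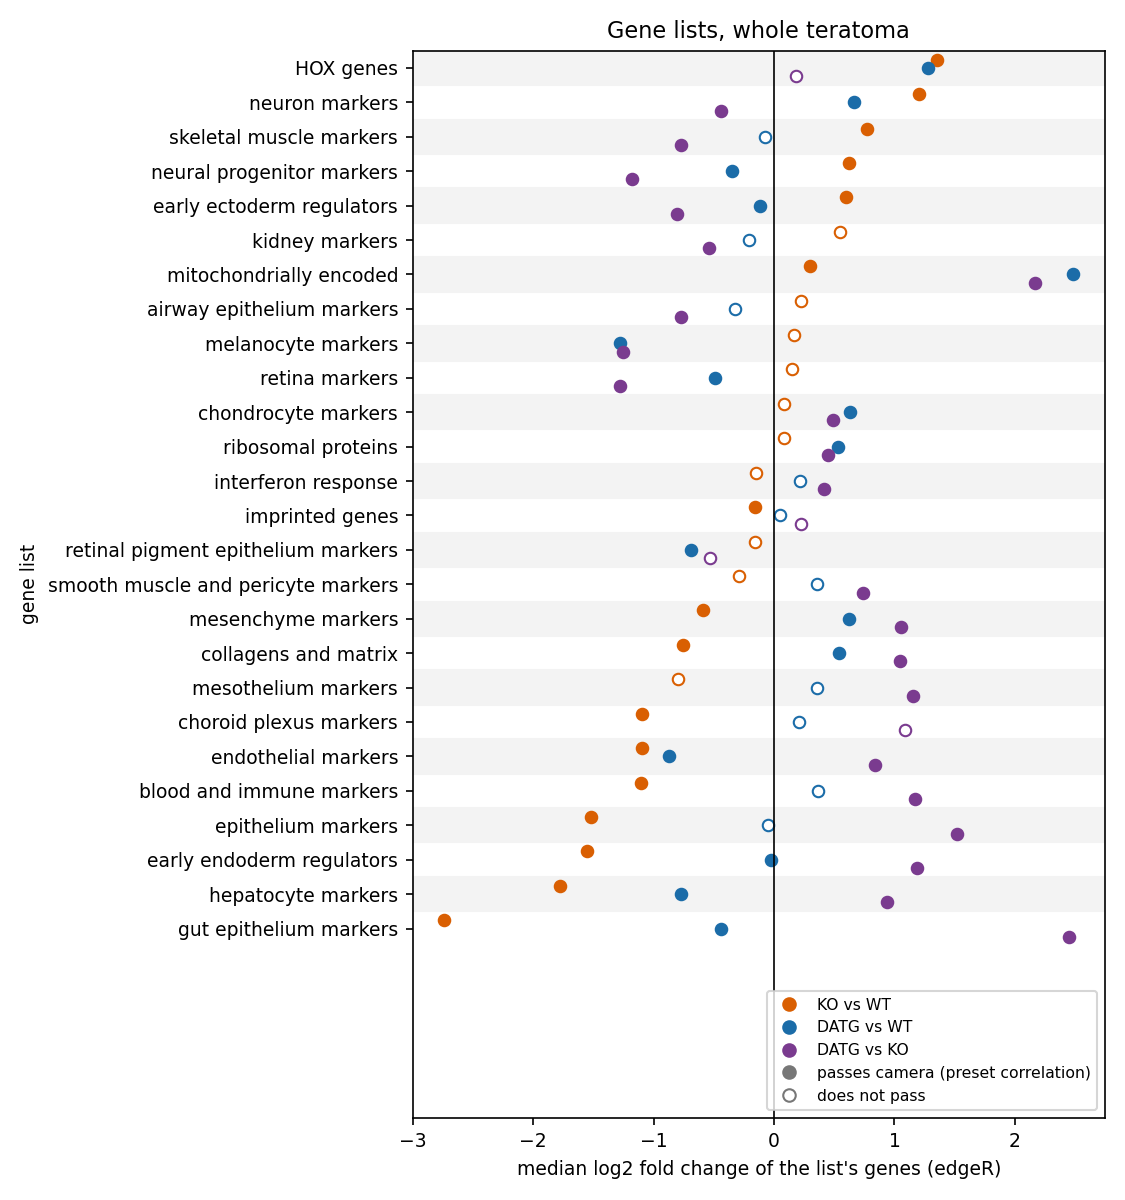
Median log2 fold change (x axis) of each gene list that passed in at least 1 comparison (y axis), with 1 point for each of the 3 comparisons, coloured by comparison. Filled points pass camera with its preset correlation, as for gut epithelium at -2.74 in KO vs WT, and open points do not.

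Melanocyte-like nuclei were 1.96% ± 0.920 of WT and 0.118% ± 0.0625 of DATG nuclei (log2 fold change -4.05, edgeR adjusted p = 0.104), the smallest p among the 16 classes. No class passed in DATG vs WT, with 1 at an unadjusted p under 0.05. The DATG pair differed in makeup: gut epithelium-like nuclei were 0.675% and 14.3%, general epithelium-like nuclei 5.73% ± 8.07 and neuron-like nuclei 19.4% and 5.18%. In DATG replicate 2, 35.5% of barcodes were mixed between human and mouse, and mouse RNA made up 2.52% of the UMIs of its human nuclei, against 0.480% to 1.08% in the other libraries.

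For single genes edgeR called 0 of 26146 in DATG vs WT (744 at an unadjusted p under 0.05), while DESeq2 called 83, with 22 higher and 61 lower. The genes with the smallest p did not pass in edgeR (adjusted p from 0.756 to 0.972). H19, an imprinted non-coding RNA on chromosome 11 (1995176 to 2001470, minus strand), stood at 108 ± 40.2 CPM in WT and 0.907 ± 0.108 in DATG, a log2 fold change of -6.87 (SE 0.66; DESeq2 adjusted p = 3.4e-24). CHCHD2, a nuclear gene for a mitochondrial protein on chromosome 7 (56101569 to 56106576, minus strand), stood at 18.2 ± 8.66 and 0.501 ± 0.205 (-5.12; DESeq2 adjusted p = 6.0e-13). CLPS stood at 35.4 ± 5.45 and 0.745 ± 0.382 (-5.52), and the neuropeptide S receptor NPSR1 at 10.5 ± 1.85 and 0.980 ± 0.125 (-3.42). Higher in DATG were HBE1, the embryonic epsilon globin, at 0.419 ± 0.0732 and 43.7 ± 18.9 CPM (6.69), MT-ATP6 at 89.9 ± 40.5 and 504 ± 56.7 (2.49), BRINP1 (1.55) and NELL1 (1.28). The annotated span of HBE1 overlaps other genes, so its value is uncertain. Of its 1855 and 512 UMIs in the DATG libraries 1499 and 366 lay in 1 cluster. There 8 and 9 nuclei held any UMI of HBE1, HBG2, HBZ or HBA2, and only 3 and 7 held at least 3. Without DATG replicate 1 edgeR called 1985 genes, 335 higher and 1650 lower, and without DATG replicate 2 73, 32 higher and 41 lower. Each of these counts describes 1 DATG library, assumed to vary like the other groups.

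In DATG against KO teratomas, connective tissue markers were higher and neural progenitor and pigment cell markers lower, and gut and epithelial markers were higher mainly through DATG replicate 2. The gut list rose by a median of 2.45 (12 of 14 above 0) and the epithelium list by 1.52 (13 of 13), but without DATG replicate 2 by 0.44 (camera adjusted p = 0.00438) and -0.11 (adjusted p = 0.870). Gut and general epithelium-like nuclei were 14.3% and 11.4% of that library, against 0.675% and 0.0185% of DATG replicate 1. The mesenchyme list rose by 1.05 (16 of 16) and collagens and matrix by 1.05. COL1A1, the main collagen of connective tissue, stood at 481 ± 421 CPM in KO and 2069 ± 537 in DATG. Neural progenitor markers fell by -1.18 with 0 of 16 above 0 and 8 past the threshold when adjusted over the list alone, among them NR2E1, a regulator of neural stem cells, at 13.2 ± 3.43 and 2.02 ± 0.0936 CPM. Melanocyte markers fell by -1.25 with 2 of 8 past the threshold when adjusted over the list alone. With all libraries the camera adjusted p was 6.5e-07, 5.2e-06, 1.4e-07, 6.3e-11, 4.0e-11 and 1.5e-07 in that order, and with an estimated correlation adjusted p = 0.538 for each except epithelium at 0.570. The mesenchyme and collagen medians were 0.67 and 0.50 without KO replicate 1 and 1.79 and 2.05 without KO replicate 2, and the melanocyte median was -2.03 without DATG replicate 1.

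The mitochondrial list rose by 2.16 (13 of 13 past the threshold when adjusted over the list alone, camera adjusted p = 2.5e-24; adjusted p = 0.538 with an estimated correlation) and ribosomal proteins by 0.45 (3.55e-04; adjusted p = 0.914 with an estimated correlation). Also higher were early endoderm regulators (1.19), blood and immune (1.17, with the fetal globin HBG1 at 6.72), mesothelium (1.16), hepatocyte (0.94), endothelial (0.84), smooth muscle and pericyte (0.74), chondrocyte (0.49) and interferon response (0.42) lists. In that order the camera adjusted p was 0.00567, 3.5e-05, 0.0107, 0.00402, 0.0172, 0.00623, 0.0390 and 0.0390, and with an estimated correlation adjusted p = 0.570, 0.538, 0.538, 0.591, 0.570, 0.566, 0.538 and 0.760. Lower were retina (-1.28), early ectoderm regulators (-0.81, 0 of 23 above 0, PAX6 -1.18), skeletal muscle (-0.78, the sarcomere protein TTN -1.01), airway epithelium (-0.77), kidney (-0.54) and neuron (-0.44) lists. Their camera adjusted p was 0.00402, 7.5e-09, 0.00567, 0.0172, 0.0347 and 0.00214, and with an estimated correlation adjusted p = 0.538, 0.538, 0.640, 0.538, 0.594 and 0.760. With 1 library left out the mitochondrial list kept its call and its median within 1.5 times. Of the other lists in this paragraph 9 did not pass with DATG replicate 1 left out: ribosomal (-0.61), interferon (-0.18), retina (-1.63), chondrocyte (0.057), skeletal muscle (-1.17), smooth muscle and pericyte (0.48), kidney (-1.13), mesothelium (1.10) and airway (-1.96). With DATG replicate 2 left out, endoderm regulators (-0.39), neuron (0.19), endothelial (0.18), kidney (-0.21) and airway (-0.21) did not pass. With KO replicate 1 left out, interferon (0.31), chondrocyte (0.48), skeletal muscle (-0.61), smooth muscle and pericyte (0.49), endothelial (0.62), kidney (-0.36) and hepatocyte (0.48) did not, and with KO replicate 2 left out, ribosomal (0.16), interferon (0.34) and airway (-0.85) did not. The interferon list (0.42) did not pass without either WT library. Medians that passed but moved by over 1.5 times were those of ectoderm (-1.40), neuron (-1.69) and endothelial (1.28) without DATG replicate 1, of ribosomal (1.03), interferon (0.72), retina (-0.76), blood (0.50) and hepatocyte (0.62) without DATG replicate 2, of ribosomal (0.81) and retina (-0.77) without KO replicate 1, and of skeletal muscle (-1.21), blood (2.60) and hepatocyte (1.43) without KO replicate 2.

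Melanocyte-like nuclei (log2 fold change -4.28, edgeR adjusted p = 0.0855) and neural progenitor-like nuclei (10.6% ± 3.88 of KO, 1.59% ± 1.35 of DATG; adjusted p = 0.282) had an unadjusted p under 0.05, and 0 of 16 classes passed. With DATG replicate 1 left out 7 classes passed, 2 of them higher in DATG (gut and general epithelium) and 5 lower, but DATG is then 1 library, assumed to vary like the other groups, and the calls describe that library alone. Among single genes edgeR called 0 of 26146 (1363 at an unadjusted p under 0.05), and DESeq2 69, with 49 higher and 20 lower. The named genes did not pass in edgeR (adjusted p = 0.717). ZNF667 (5.64), HBE1 (6.32), FOLH1 (3.99) and HSD17B7P2 (2.55), a pseudogene that may share reads with its parent gene, stood higher in DATG. H19 (-5.48), CHCHD2 (-5.12), the melanin enzyme DCT (-3.74; 35.2 ± 13.7 CPM in KO, 2.62 ± 0.514 in DATG) and MMRN1 (-1.82), a protein of platelets and endothelium, stood lower. Without DATG replicate 1 the count was 6028, with 2249 higher and 3779 lower, and without DATG replicate 2 it was 3, again for a single DATG library each.

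Several gene groups passed in none of the comparisons. Given as medians for KO vs WT and DATG vs WT, these were pluripotency genes (0.35, 0.50), pluripotent markers (0.35, 0.60), p53 targets (-0.10, 0.064), glycolysis and hypoxia (-0.23, -0.071), early mesoderm regulators (0.34, 0.38), S phase (-0.19, -0.20) and G2 and M phase genes (0.085, -0.055), and immediate early and heat shock genes (0.22, 0.016). Among signalling lists they were WNT (-0.026, 0.16), BMP and TGF-beta (0.046, 0.012), NOTCH (-0.062, -0.14), FGF and ERK (0.013, -0.36) and Hedgehog (-0.067, -0.17). Among cell markers they were astrocyte (-0.20, 0.20), oligodendrocyte precursor (0.42, 0.33), Schwann and neural crest (0.43, 0.38), squamous epithelium (-0.068, -0.26), osteoblast (-0.026, 0.28), cardiomyocyte (-0.038, 0.39), gastric epithelium (0.27, -0.16), enteroendocrine (0.19, -0.16), ciliated epithelium (-0.12, 0.13) and trophoblast (0.51, 0.10). The lists not passing numbered 33, 33 and 27 in KO vs WT, DATG vs WT and DATG vs KO, with camera adjusted p from 0.0508 to 0.994, 0.0749 to 0.958 and 0.104 to 0.994. The smallest were interferon response, immediate early genes and oligodendrocyte precursors in KO vs WT, and imprinted genes in DATG vs WT, where 3 members passed when adjusted over the list alone. Median, mean and direction of the test differed in sign, among lists that did not pass, for the BMP, NOTCH, FGF, chondrocyte, osteoblast, gastric and enteroendocrine lists in KO vs WT. They did so for the immediate early, imprinted, choroid plexus, skeletal muscle, gastric and epithelium lists in DATG vs WT, and for the pluripotency, HOX, S phase, Hedgehog, osteoblast and enteroendocrine lists in DATG vs KO.

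Within single classes the comparison removes the mix of classes but not that of clusters in a class or free RNA of other classes in the droplets. In mesenchyme-like nuclei edgeR called 0 of 20210 genes in KO vs WT and in DATG vs WT (777 and 559 at an unadjusted p under 0.05), and DESeq2 57 and 49. Most WT mesenchyme-like nuclei, 63.6%, were in cluster 1 and most of KO, 68.3%, in cluster 0, with nuclei pooled by group. The DATG libraries differed from each other. Those of replicate 1 lay mainly in clusters 0 and 7 (18.7% and 14.4% of its human nuclei). Those of replicate 2 lay mainly in clusters 5 and 16 (23.6% and 12.1%). Of neuron-like nuclei pooled by group, cluster 11 held 12.0% in WT, 26.4% in KO and 22.5% in DATG, and cluster 9 32.6%, 21.8% and 26.9%. For cluster 9 the WT libraries differed from each other, at 0.749% and 3.40% of human nuclei, while their neuron-like nuclei were 7.10% and 8.15%. A shift of cluster 9 between groups can therefore not be read from the pooled values. In neuron-like nuclei edgeR called 0 of 18516 (369 and 420; DESeq2 2 and 6), and in choroid plexus-like nuclei 0 of 13606 (183 and 288; DESeq2 2 and 0). H19 stood at 151 and 237 CPM in the WT libraries, 67.5 and 149 in KO and 2.53 and 1.38 in DATG mesenchyme-like nuclei. CHCHD2 stood at 12.8 and 20.5 CPM in WT, 21.3 and 15.9 in KO, and 0.148 and 0 in DATG neuron-like nuclei. The mesenchyme count was 10 for KO vs WT without either DATG library, and 201 for DATG vs WT without DATG replicate 1, where it describes DATG replicate 2 alone.

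Host cells made up 1.46% ± 0.473 of kept nuclei in WT, 2.89% ± 1.46 in KO and 4.48% ± 5.32 in DATG (0.714% and 8.24%). The differences from WT, 1.43 and 3.02 percentage points, had exact 2-sided permutation p = 0.333, the smallest this design allows, and p = 1. They depended on the purity asked of a nucleus and on single libraries: KO minus WT was 0.232 points at 80% purity, -1.48 at over 50%, 2.46 without KO replicate 1 and 0.401 without KO replicate 2, and DATG minus WT was 4.85, 7.88, 6.79 without DATG replicate 1 and -0.742 without DATG replicate 2. Macrophage-like nuclei were 14.0%, 21.1% and 20.5% of mouse nuclei in WT, KO and DATG, and fibroblast-like nuclei 21.7%, 18.5% and 9.51%. Of 8930 mouse genes edgeR called 3 in DATG vs WT, all higher: the mitochondrial genes mt-Nd3 (log2 fold change 3.80), mt-Cytb (2.92) and mt-Nd4 (2.83), each at adjusted p = 0.0300. It called 0 in KO vs WT (456 at an unadjusted p under 0.05), and DESeq2 called 19 and 11. Without either of the WT libraries the edgeR count for DATG vs WT was 0, and for the single DATG library left it was 68 without DATG replicate 1 and 21 without DATG replicate 2. The count for KO vs WT was 2 without either DATG library.

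The KO and DATG effects against WT correlated across 26146 genes, which are not independent replicates, at Pearson 0.292 and Spearman 0.138. Simulated unchanged groups against the same WT libraries gave 0.493 and 0.464. The covariance was 0.133, against a simulated 0.211 with the spread of all 6 libraries and 0.0956 with that of WT and KO, so the sign of the difference depended on the spread assumed. Of the genes DESeq2 called, 37 were lower in both (0.368 by chance for independent lists) and 1 was higher in both (0.00349). Simulated unchanged groups against shared, also simulated, WT libraries had a mean of 2.12 lower and 8.62 higher genes in common with the spread of all 6 libraries. With the spread of WT and KO these means were 0.625 and 1.5. Each gene was drawn independently there, so these values hold no joint shift of many genes and cannot say how much overlap shared controls give. With a different WT library for each comparison, so that each rests on 1 control library, 6 and 2 lower genes were shared in the 2 possible splits, and 0 and 1 higher. With these splits the Pearson correlation was 0.00584 and 0.0773 and the covariance 0.00382 and 0.0477, so part of the overlap and correlation may come from the shared controls. Without DATG replicate 1 the Pearson correlation was -0.242, and without DATG replicate 2 0.657.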

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

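Of the tests in this part, those of the labels and of the gap in gut share between the DATG libraries were chosen only after the result was seen, and that of the gut share of DATG replicate 2 against WT among nuclei with little mouse RNA was set before its value was known. The share of barcodes mixed between human and mouse, which no comparison uses, was 35.49% in DATG replicate 2, above the 13.2% and 8.12% of the WT controls, the 4.75% and 7.62% of KO and the 7.36% of DATG replicate 1. That library also had the most host nuclei, 547, and the most mouse RNA in its human nuclei, 2.52%.

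The DATG teratomas differed in makeup, with endoderm epithelium at 0.999% and 16.3% of nuclei and neuron-like nuclei at 19.4% and 5.18%. Against a wrong label on either of them stand 2 genes, H19 and CHCHD2. In this pair both were at least 4-fold below the other 4 libraries in all 3 tested classes, with 1 CPM added to each value. Neither library shared such a lower gene with a library of another group. The WT pair and the KO pair also shared 0, so this absence cannot speak against a wrong label. DATG replicate 1 shared 1 gene higher in this way, MYL11, with KO replicate 1. The log2 CPM of DATG replicate 1 also correlated more with KO (0.971 and 0.980) than with DATG replicate 2 (0.903). Against mouse RNA in human nuclei as the cause of the gap in gut share stand nuclei with at least 99% human UMIs, 7.77% of DATG replicate 2 and 60.2% to 89.0% of the others: among them the exact 95% interval of that share began at 7.315% in DATG replicate 2 and ended at 0.906% in replicate 1. For the excess of DATG replicate 2 over WT, the share among its 431 such nuclei was 9.977%, against 7.15% and 8.49% in WT. By the rule set before, staying over the higher WT library speaks against mouse RNA as the cause. The interval of that share, 7.315% to 13.2%, includes 8.49%, so mouse RNA stays open here. This look at the interval was not part of the rule set before. Differences between single tumours of one line, or between clones, remain open and were not tested.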

How the results depend on the processing

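Alternatives added after the data were seen were purity of 80% for whole teratomas and of over 50% for the host share, the limit on mitochondrial UMIs, the class shares of compared groups alone and a different WT library for each comparison in the correlation, and all others were chosen before. For the count of 0 genes in KO vs WT, DATG vs WT and DATG vs KO, DESeq2 gave 156, 83 and 69, and the libraries of the compared groups alone gave 436 in KO vs WT. Leaving out 1 library gave 0 to 592, 0 to 1985 and 0 to 6028, all above 0 from leaving out a DATG library, where the coefficient of biological variation fell from 38.6% to 24.4%. The counts of 16, 16 and 22 lists came to 0 in each comparison both with an estimated correlation and with fry, and to 14 to 23, 8 to 22 and 19 to 28 with 1 library left out. List medians reversed without DATG replicate 1 in DATG vs WT (early endoderm 0.37, ribosomal -0.57, neuron -0.57, gut 0.15) and in DATG vs KO (ribosomal -0.61, interferon -0.18), without DATG replicate 2 in DATG vs KO (early endoderm -0.39, neuron 0.19), and without WT replicate 2 in KO vs WT (mitochondrial -0.056). Medians also turned in sign, with the direction of the test kept but its call lost, in KO vs WT for blood (0.40 without WT replicate 2) and imprinted genes (0.016 without KO replicate 1), in DATG vs WT for ectoderm regulators (0.0048) and retinal pigment epithelium (0.19) without WT replicate 1, early endoderm (0.084 without WT replicate 2) and chondrocyte markers (-0.46 without DATG replicate 1), and in DATG vs KO for epithelium (-0.11 without DATG replicate 2). The ranges with 1 library left out were -0.056 to 1.10 for mitochondrial genes in KO vs WT. In DATG vs WT they were -1.76 to 0.37 for endoderm, -0.57 to 1.08 for ribosomal, -0.57 to 1.27 for neuron and -2.12 to 0.15 for gut, and in DATG vs KO -0.39 to 1.46 for endoderm, -0.61 to 1.03 for ribosomal, -0.18 to 0.72 for interferon and -1.69 to 0.19 for neuron. Class shares in DATG vs KO gave 0 to 7 and 0 in the other comparisons, and no value for the pluripotent-like share at resolution 0.5. Within mesenchyme-like nuclei DESeq2 gave 57 and 49 genes for KO and DATG vs WT and no filter 20 and 19, with 0 to 10 and 0 to 201 when 1 library was left out. Within neuron-like nuclei DESeq2 gave 2 and 6 and no filter 63 and 69, and within choroid plexus-like nuclei DESeq2 gave 2 for KO and no filter 25 and 47, both classes at 0 with any library left out. For mouse genes DESeq2 gave 11 and 19, no filter 65 and 171, and 1 library left out 0 to 2 and 0 to 68. The correlation of effects was 0.171 over genes with a mean of at least 10 CPM, 0.00584 and 0.0773 with a different WT library for each comparison, and -0.242, reversed, to 0.657 with 1 library left out. The mouse share of KO minus WT was 0.232 points at 80% purity, -1.48 at over 50% and 0.401 to 2.46 with 1 library left out, and DATG minus WT -0.742, reversed, to 6.79. LNCPRESS1 ranged from -4.96 to -0.36, -5.07 to 0.39 and -3.70 to 4.02. Of 240 values of named genes under other settings 214 stayed on their side of the threshold and 26 came past it. The 26 kept their direction, while a change of direction among the 214, which did not pass, was not counted. Of 216 list values 105 kept their call and 111 lost it, 108 of them to the estimated correlation and fry. For every change named here beyond that of the spread the cause was not tested. Depth limits LNCPRESS1, with 14 UMIs in all, and the host comparison, with 87 nuclei in the smallest library.

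The labels do not say that the replicate numbers pair the samples. The deviations of same-numbered libraries from their group means correlated at 0.115 for WT and KO, -0.144 for WT and DATG and 0.358 for KO and DATG. With 2 libraries per group these values do not settle whether a number stands for a shared batch. With the replicate number as a block edgeR called 0 genes in each whole-teratoma and within-class comparison, 0 classes, 0 and 3 mouse genes, and camera 18, 15 and 20 lists, with LNCPRESS1 at -1.38, -0.89 and 0.48. Of the 54 list calls without the block, 51 were kept and 3 lost.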

Other observations

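The tests in this part were chosen only after the results were seen. Among the leading genes of 1 unnamed cluster of 2870 shallow nuclei (median 989.5 UMIs) were HBE1, HBG2, HBZ, HBA2 and heat shock genes. Only 46 of its nuclei held any UMI of these 4 globins, and 17 DATG nuclei held 4107 of the 4150 UMIs of these 4. That cluster held 9.42% ± 0.256 of WT, 4.89% ± 0.307 of KO and 3.29% ± 0.291 of DATG nuclei. In whole teratomas HBE1 stood at 0.370 and 0.473 CPM in WT, 0.161 and 0.929 in KO, and 57.3 and 29.7 in DATG. HBG2 stood at 0.437 and 4.475 in WT, 0.225 and 0.993 in KO, and 38.0 and 4.53 in DATG, and HBZ at 0.336 and 0.378, 0.482 and 0.480, and 23.4 and 1.57. Among the other unnamed clusters, some were led by PAX3 and PAX7 (2950 nuclei), by the glycine transporter SLC6A5 with PAX8 and PAX2 (964 nuclei), and by mitotic genes such as CENPE and ASPM (855 nuclei), and MEG8 and MEG3 were among the leading genes of 1 more (777 nuclei, 677 of them in WT, 50 in KO and 50 in DATG). In the host, 1 unnamed cluster led by Inhba, Tnc and Mmp13 had 140 nuclei in KO, of which 125 came from KO replicate 2, against 3 in WT and 2 in DATG. Nuclei of this cluster were not compared by a test.

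The imprinted gene IGF2 stood at 41.1 ± 17.4 CPM in WT, 16.7 ± 14.7 in KO and 194 ± 175 in DATG, and did not pass over all genes in edgeR.

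Mitochondrial transcripts were higher in both DATG libraries. Against the mix of cell classes as the whole cause stands the median log2 fold change within the 3 tested classes, beside 2.54 in the whole teratoma. It was 2.655 in mesenchyme-like, 1.715 (the middle value) in neuron-like and 1.467 in choroid plexus-like nuclei. In the last class the rise did not hold in both DATG libraries for MT-ATP6. Its CPM there was 490 and 141 in DATG, 162.5 and 44.4 in WT, and 298 and 71.7 in KO. Against mouse RNA in human nuclei stands DATG replicate 1, with 0.488% of such RNA, whose mitochondrial percent was 2.689 times that of the highest WT or KO library. Carry-over of cytoplasm during preparation of nuclei remains a candidate explanation, since the mitochondrial genes of the host nuclei, which carry no edit, were higher by a median log2 fold change of 2.592 in the same libraries. A biological effect of the DATG line on human mitochondria remains untested.

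Several genes were near absent in both libraries of a group, among them ZNF667 and FOLH1 in KO and H19 and CHCHD2 in DATG, while ZNF585B was lower in KO but not absent. Against loss of a cell class with its free RNA stands the median log2 fold change of -3.951 that H19, CHCHD2, ZNF667 and ZNF585B kept in the cluster where each was highest in WT: -3.68 for ZNF667 (17 UMIs in 243 WT nuclei, 0 in 740 of KO), -4.22 for CHCHD2 (84 and 1 UMIs), -1.999 for ZNF585B, resting on 1 UMI in 62 KO nuclei, and -8.30 for H19, where 104 of 111 WT and 634 of 636 DATG nuclei came from replicate 2. For APOA1 and CLPS the same test gave -0.629 and so is in line with that explanation, and FOLH1 (-3.44, 2 UMIs in 62 KO nuclei) and NPSR1 (-1.33, 4 UMIs in 50 DATG nuclei) were in neither set. Against reads moved to the copy ZNF585A stands that gene's own log2 fold change of -0.8826, while a changed H19 and IGF2 domain stays open for H19, with IGF2 higher by a median of 1.409 over the 3 classes but with values that overlapped those of WT in neuron-like and choroid plexus-like nuclei. Chance differences between single tumours or clones cannot be told apart from an effect of the edit. A count of genes at least 4-fold below the other 4 libraries in all 3 tested classes with 1 CPM added did not settle this. Pairs from different groups shared 0 such genes and the DATG pair 2, H19 and CHCHD2, but the KO pair also shared 0. That 0 rests on the added 1 CPM. ZNF667 missed the rule only in choroid plexus-like nuclei, at 1.35 and 0 CPM in KO and at least 8.22 in the other libraries.

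A hypothesis that a whole autosome or X was gained or lost in all nuclei of a line, which could shift many genes, gave a negative result. The largest median log2 difference of chromosomes 1 to 22 and X from WT was 0.07031 in size over 8726 genes, against 0.585 for 3 copies in place of 2.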
